A study of Homo sapiens with 8 samples.

How the data were processed

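The labels describe RNA sequencing of human trophoblast stem cells, the self-renewing precursors of the placental epithelium. The cells carried a lentiviral short hairpin RNA (shRNA) and were driven for 8 days toward extravillous trophoblast, the invasive placental cell that enters the uterine wall. Per the labels, 4 libraries carried a scrambled control hairpin and 4 a hairpin against TFPI, the gene of tissue factor pathway inhibitor, an inhibitor of blood coagulation. Total RNA was made into Illumina TruSeq libraries and sequenced as 100-bp paired-end reads, per the labels' protocols.

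The processed table given for this series did not match those labels, and this decided what was computed. It held 33654 rows named as transcripts, with identifiers of rat type. It had 6 library columns, 3 named as scrambled and 3 as Tfpi knockdown, against 8 libraries in the labels. The column numbered 4 was named as a knockdown, whereas the labels number a control 4. The 6 library columns of RPKM values were therefore assigned to none of the 8 labelled libraries and were not used in any test. No value was assigned to any of the 8 human libraries, so no depth, replicate spread, standard deviation or sample-level test is given.

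What was used were the authors' own comparison columns. The fold change in the deposited table is a signed score: its size is a ratio of at least 1, and a minus sign marks the direction. From the order in the header, scrambled against Tfpi knockdown, and from the minus sign of both Tfpi transcripts, a minus was read as lower in the knockdown. The deposited p-value and false discovery rate (FDR) come from a test called EDGE with tagwise dispersions, per the file headers. How much spread between libraries these p-values took in was not checked here. A small fold with a very low FDR is therefore not shown to be repeatable. The labels' protocols name CLC Genomics Workbench 12.0 and the rat reference Rnor_5.0 of Ensembl release 78, and the submitters' processing notes list the builds Rnor_5.0 and GRCh37. Which of them produced this table, the kind of cells, the read counts behind each row and how reads shared by several transcripts were divided are not given in the sources used here. Transcripts of 1 gene and genes with near-identical copies can share reads, so values for such families are uncertain. No coordinates are given, because no rat annotation was used here.

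From these columns, a transcript was called when the deposited FDR was below 0.05, the threshold the labels name. Recomputing Benjamini-Hochberg values from the deposited p-values gave the deposited FDR to within 1.75e-14. Symbols were taken as the row name without its final transcript number. The 30 gene lists, written with human symbols before the data were examined, were matched to rat symbols of the same spelling in any letter case, which names the gene of the same symbol and was not checked against an orthology table. For each list, a one-sided Fisher's exact test compared called genes among its members with called genes among the 16910 genes that had a transcript with a fold other than 1, leaving out Tfpi, and Benjamini-Hochberg adjustment ran over the 30 lists. Genes are not independent replicates, and abundant genes are called more easily, so these tests describe this table only. Calls were also adjusted over the list alone.

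The plan fixed before the data were examined was a model over 8 libraries, with set tests on their log values, a permutation test of TFPI, other scalings, filters and pseudocounts, and leaving out each library. None of these was run, because the library columns matched no labelled library. The Fisher tests and the reading of the authors' columns replaced them and were chosen after seeing the data. The rule for named genes was kept as far as the authors' comparison columns allowed. It named Tfpi, the 8 named genes with the largest falls and the 8 with the largest rises among called transcripts. It also named up to 4 members per list with the lowest p. Its requirements on a minimum level and on non-overlapping groups were not applied. They need library values, and the RPKM columns that hold such values were left unused by choice. Genes named outside this rule are said to be so.

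Alternatives were a fold of at least 2, Bonferroni correction, adjustment over rows with a fold other than 1, counting gene symbols, and a list background of genes with a p-value below 1. The adjustment was tested on simulated p-values for 33654 transcripts, with a large shift given to 200 of them. Of these, 98.5% were recovered, and 5.7% of calls were false. The unshifted simulated p-values were spread evenly. In the deposited table, 55.5% of transcripts with a fold other than 1 had a p-value of exactly 1. The simulated rates therefore check the adjustment only and do not carry over to the deposited p-values. Separately, 0.5% of 1000 random lists of made-up genes had a Fisher p under 0.05. These lists were drawn evenly, so they do not test the easier calling of abundant genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.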

Results

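The labels set 4 human libraries with a control shRNA against 4 with an shRNA against TFPI, after 8 days of differentiation toward extravillous trophoblast, and so ask how the loss of TFPI alters the transcripts of these cells. The processed table of the series does not answer that question for the human cells. Of its 33654 rows, 33 (0.0981%) carried a name spelled as a human gene symbol with its letter case, and 21300 (63.3%) did so when case was ignored, since rat and human genes share many symbols. In addition, 4627 rows had clone names beginning with AABR07, 680 had RGD names, 103 belonged to RT1, the rat major histocompatibility complex, and 48 had rat Ensembl gene identifiers. No row was named for an HLA gene. The table compared 3 scrambled with 3 Tfpi knockdown libraries, whose columns could not be matched to the 8 labelled ones. What follows is the comparison that the authors' deposited table records for rat-annotated transcripts. Its fold columns carry no standard errors, and its library columns were not used here, so no replicate error is given. Nothing in it is treated as a measurement of the human libraries.

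Tfpi, the target, had the largest fold of all 33654 rows. Its minus sign, with the order of the groups in the header, is what set a minus as lower in the knockdown, so its direction is not an independent check of the labels. Read in this way, in the authors' deposited table, the transcript Tfpi_1 was 37.9-fold lower, with a p-value listed as 0, and Tfpi_2 was 9.44-fold lower (FDR = 1.61e-132). For Tfpi2, which encodes a related protease inhibitor and was looked up after the values were seen, the authors' deposited table gave a fold of 1.14 upward with an FDR of 1.0.

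Across the table, 193 transcripts of 182 gene symbols passed the authors' FDR of 0.05. Of these, 137 were lower and 56 higher in the knockdown. Most changes were small: the median size in the authors' deposited table was 1.63-fold for the lower and 1.44-fold for the higher transcripts. At least a 2-fold change was listed for 52 lower and 12 higher transcripts. An unadjusted p below 0.05 was listed for 661 transcripts.

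After Tfpi, the largest falls among called transcripts of named genes in the authors' deposited table were those of Rpl39l, a ribosomal protein paralog (5.69-fold, FDR = 4.14e-24), Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1 (5.05-fold for Ppp1r3b_2, FDR = 0.00363), and Pfpl (4.53-fold, FDR = 1.79e-18). Glipr2 was 4.40-fold lower in the authors' deposited table (FDR = 0.000618), and Plpp3, a lipid phosphate phosphatase, was 4.25-fold lower (FDR = 0.0151). Esam, an endothelial cell adhesion molecule, fell 4.34-fold as transcript Esam_2 in the authors' deposited table (FDR = 1.1e-07). Crispld2, a secreted protein, fell 3.81-fold as transcript Crispld2_2 (FDR = 6.31e-102) and Ceacam3 fell 3.59-fold (FDR = 0.000155) in the authors' deposited table. Other transcripts of these genes were listed in the authors' deposited table with larger falls without passing: Ppp1r3b_1 6.24-fold (FDR = 0.189), Esam_1 9.82-fold and Crispld2_3 8.00-fold. The last pair had an FDR of 1.0 and an unadjusted p of 0.25 each in the authors' EDGE test. Crispld2_1 had a fold of 1.0 in the authors' deposited table. No minimum level was applied and read counts are not known here, so the larger falls may rest on few reads.

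Among the rises, the authors' deposited table listed Grcc10 at 36.1-fold, with an FDR of 0.0437 that lay just inside the threshold. As no minimum level was applied and its read counts are not known here, this size may rest on few reads. Evpl, which encodes the cornified envelope protein envoplakin, was 9.49-fold higher in the authors' deposited table (FDR = 1.6e-18). The glycolytic enzyme gene Aldoa was 3.84-fold higher as transcript Aldoa_2 (FDR = 0.00258), whereas Aldoa_1 and Aldoa_3 had folds of 1.17 and 1.05 with an FDR of 1.0 in the authors' deposited table. Des, the muscle intermediate filament desmin, was 2.89-fold higher (FDR = 0.033), Rbp7, a retinol-binding protein, 2.79-fold (FDR = 9.39e-16) and Fgfbp1, a carrier of fibroblast growth factors, 2.61-fold (FDR = 3.45e-17) in the authors' deposited table. Emb, a cell adhesion glycoprotein, was 2.57-fold higher as Emb_1 (FDR = 0.0441), whereas Emb_2 was listed 1.01-fold lower with an FDR of 1.0 in the authors' deposited table. Pam, an enzyme that amidates peptide hormones, was higher as both Pam_1 (2.28-fold, FDR = 0.000922) and Pam_2 (2.11-fold, FDR = 1.19e-10) in the authors' deposited table.

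**Figure D1:**
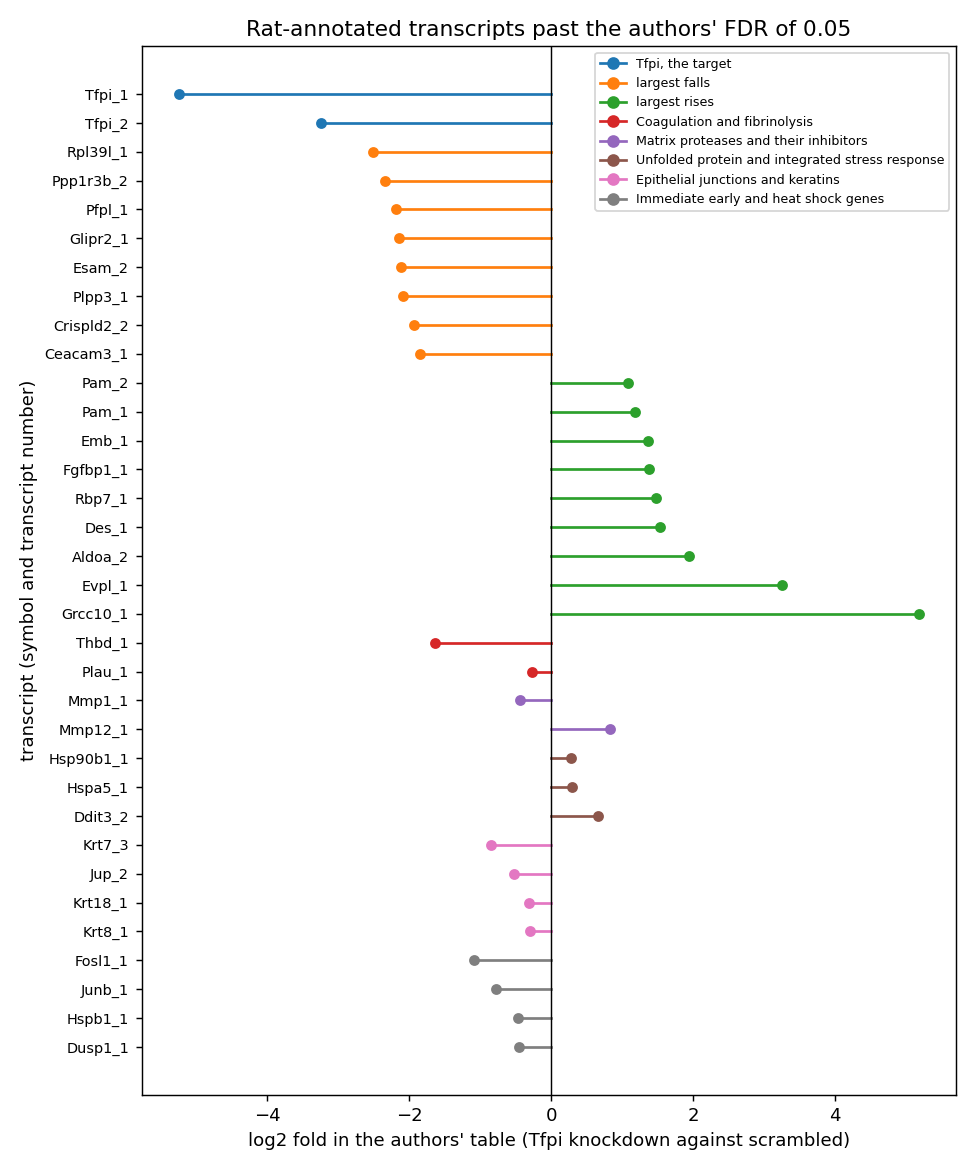
Log2 fold in the authors' table, Tfpi knockdown against scrambled (horizontal axis), for called rat-annotated transcripts (vertical axis), coloured by the rule or gene list that named them; each point is the authors' single value, without error. Tfpi_1 lies farthest to the left at -5.24 and Grcc10_1 farthest to the right at 5.17.

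Immediate early and heat shock genes were the list with the most called members, and all of these were lower. Of 23 measured members, 5 were called lower and none higher (one-sided Fisher's exact test, adjusted p = 0.000115 over 30 lists). When adjusted over the list alone, 8 members passed. Of the list's 29 transcripts with a fold other than 1, called or not, 82.8% were lower, and this share was not tested. In the authors' deposited table, Fosl1, a subunit of the AP-1 transcription factor, fell 2.12-fold (FDR = 7.01e-09), Junb, another AP-1 subunit, 1.71-fold (FDR = 0.000506), Dusp1, a phosphatase of MAP kinases, 1.36-fold (FDR = 0.00326), and Hspb1, a small heat shock protein, 1.38-fold (FDR = 0.0141). The fifth was Myc, a growth-promoting transcription factor, which fell 2.14-fold as Myc_2 in the authors' deposited table (FDR = 0.0185). Under Bonferroni correction only 1 of these members was called and the list's adjusted Fisher p was 0.516. With calls limited to folds of at least 2 it was 0.0782.

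Of 31 measured members of the list of epithelial junctions and keratins, 4 were called, all lower (Fisher's exact test, adjusted p = 0.00478), with 6 called when adjusted over the list alone. Of its 42 transcripts with a fold other than 1, called or not, 50.0% were lower. Krt7 fell 1.81-fold as Krt7_3 (FDR = 2.79e-10), Krt8 1.23-fold (FDR = 0.000199), Krt18 1.24-fold with an FDR listed as 0, and Jup, which encodes plakoglobin, 1.44-fold as Jup_2 (FDR = 0.0441) in the authors' deposited table. None of these folds reached 2.

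In the list of unfolded protein and integrated stress response genes, 3 of 31 measured members were called, all higher (Fisher's exact test, adjusted p = 0.039). The same number was called when adjusted over the list alone. Of the list's 36 transcripts with a fold other than 1, called or not, 52.8% were lower. The chaperone Hspa5 was 1.23-fold higher (FDR = 1.83e-08), Hsp90b1 1.21-fold (FDR = 0.000376), and Ddit3, a transcription factor of the stress response, 1.59-fold as Ddit3_2 (FDR = 9.15e-05) in the authors' deposited table. Atf4 did not pass, at 1.15-fold lower with an FDR of 0.93 in the authors' deposited table. Against the background of genes with a p-value below 1, this list's adjusted p was 0.148, and none of its called folds reached 2.

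Of 33 measured hypoxia and glycolysis genes, 2 were called lower and 1 higher (Fisher's exact test, adjusted p = 0.039), with 6 called when adjusted over the list alone. Of the list's 52 transcripts with a fold other than 1, called or not, 36.5% were lower. Cited2, a hypoxia-induced transcriptional regulator, fell 1.63-fold (FDR = 8.25e-17), the glycolytic Eno1 fell 1.14-fold as Eno1_2 (FDR = 7e-05), and the riser was Aldoa_2 in the authors' deposited table. This list's adjusted p was also 0.148 against genes with a p-value below 1, and 0.0901 under Bonferroni calls.

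In the coagulation and fibrinolysis list, which left out Tfpi, 2 of 30 measured members were called, both lower (Fisher's exact test, p = 0.0407, adjusted p = 0.196). Adjusted over the list alone, 4 were called. Of its 37 transcripts with a fold other than 1, called or not, 29.7% were lower. Thbd, encoding the anticoagulant receptor thrombomodulin, fell 3.11-fold (FDR = 4.66e-09) and Plau, encoding urokinase, 1.21-fold (FDR = 1.7e-05) in the authors' deposited table. Serpine2, a thrombin inhibitor, was listed 3.04-fold higher as Serpine2_1 without passing (FDR = 0.066), and Procr, the protein C receptor, 1.44-fold lower without passing (FDR = 0.307) in the authors' deposited table. When the authors' p-values were adjusted over rows with a fold other than 1, 3 members were called and the list's adjusted Fisher p was 0.031.

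Matrix proteases were split: of 32 measured members, Mmp1 fell 1.36-fold with an FDR listed as 0 and Mmp12, a macrophage-type elastase, rose 1.78-fold (FDR = 6.33e-08) in the authors' deposited table (Fisher's exact test, adjusted p = 0.196). Adjusted over the list alone, 4 members were called. Mmp1b, named after its value was seen, fell 2.03-fold in the authors' deposited table (FDR = 2.01e-17), and because Mmp1 and Mmp1b are similar in sequence both values are uncertain. The adjusted Fisher p of the matrix protease list was 0.031 when the authors' p-values were adjusted over rows with a fold other than 1. Among 36 measured extracellular matrix genes none passed over all transcripts and 2 passed when adjusted over the list alone. An unadjusted p below 0.05 in the authors' EDGE test was listed for 3. Of the matrix list's 54 transcripts with a fold other than 1, 20.4% were lower, and this share was not tested. The basement membrane collagens Col4a1 and Col4a2 were listed 4.20-fold and 4.58-fold higher, each with an FDR of 0.0828, in the authors' deposited table.

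Of 26 measured extravillous trophoblast markers, 1 passed (Fisher's exact test, adjusted p = 0.611), and 1 when adjusted over the list alone: Plac8 fell 1.56-fold with an FDR listed as 0 in the authors' deposited table. Of 23 measured stem cell and cytotrophoblast markers the transcription factor gene Tfap2c fell, by 1.23-fold (FDR = 0.00776) in the authors' deposited table, and was likewise the 1 member called over the list alone (Fisher's exact test, adjusted p = 0.598). Gata2 was listed 1.54-fold lower without passing (FDR = 0.852) in the authors' deposited table. Of 12 measured cell column markers, Myc was the 1 called, by either adjustment (Fisher's exact test, adjusted p = 0.364). None of 11 measured syncytiotrophoblast markers passed by either adjustment, and 1 had an unadjusted p below 0.05 in the authors' EDGE test. These lists were written for human placenta, and 13 of the 34 syncytiotrophoblast symbols occurred in the table.

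Rodent placental gene families were examined after their values were seen, without a test of the family. Of 38 transcripts of the rodent prolactin (Prl) family, 30 had a fold other than 1. Among them, 2 were called lower and 2 called higher, both of the latter from the gene Prl5a2. In the authors' deposited table, Prl7a3 fell 3.27-fold with an FDR listed as 0, Prl2a1 fell 1.32-fold (FDR = 2.15e-05), and Prl5a2 rose 2.23-fold as Prl5a2_1 (FDR = 3.19e-13) and 2.05-fold as Prl5a2_2 (FDR = 1.01e-07). Of 16 transcripts of the Ceacam family, 12 of which had a fold other than 1, 3 were called lower and none higher. Besides Ceacam3, these were Ceacam9, 2.57-fold lower (FDR = 7.51e-06), and Ceacam15, 2.35-fold lower with an FDR listed as 0 in the authors' deposited table. Genes outside these families were also picked after their values were seen, and no group of them was tested. The trophoblast genes Hand1 (1.97-fold, FDR = 4.91e-06) and Plet1 (1.43-fold, FDR listed as 0) and the imprinted gene Mest (1.46-fold, FDR = 0.000889) were lower in the authors' deposited table. The imprinted Igf2 was lower as Igf2_1 (1.84-fold, FDR = 0.036), whereas Igf2_2 and Igf2_3 were listed 1.34-fold and 1.44-fold higher and Igf2_4 1.04-fold lower, each with an FDR of 1.0, in the authors' deposited table. Members of the Prl and Ceacam families are related genes that may share reads. Read sharing was not examined here, so their values are uncertain.

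In the p53 target list, 1 of 23 measured members rose and 1 fell (Fisher's exact test, adjusted p = 0.149), with 3 called over the list alone. Mdm2, the ubiquitin ligase of p53, was higher as Mdm2_1 (1.61-fold, FDR = 0.000519) and Mdm2_2 (1.54-fold, FDR = 0.0334), and Btg2, an antiproliferative gene, was 1.35-fold lower (FDR = 0.00222) in the authors' deposited table. Cdkn1a, the cell cycle inhibitor p21, did not pass, at 1.55-fold higher with an FDR of 0.753 as Cdkn1a_1 in the authors' deposited table.

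None of 38 measured cell cycle genes passed by either adjustment in the authors' EDGE test, and 3 had an unadjusted p below 0.05. Tyms, with the lowest p, was listed 1.43-fold higher with an FDR of 0.818 in the authors' deposited table. Of the cell cycle list's 50 transcripts with a fold other than 1, 26.0% were lower, and this share was not tested. None of 30 measured interferon response genes passed by either adjustment, and 0 had an unadjusted p below 0.05. The lists of TGF-beta targets, WNT and NOTCH pathways, antigen presentation, mesenchymal genes, inflammatory cytokines, angiogenic factors and small RNA machinery also held no called gene by either adjustment. Of these, the TGF-beta, mesenchymal and angiogenic lists each held 1 gene with an unadjusted p below 0.05, and the others held 0. The antigen presentation list was written to include major histocompatibility genes, but only 10 of its 21 human symbols occurred in the table. The 103 rows of RT1, the rat major histocompatibility complex, carry other names and were not covered by it. Cholesterol biosynthesis held no called gene over all transcripts, 1 over the list alone and 2 with an unadjusted p below 0.05. Of its 33 transcripts with a fold other than 1, 78.8% were lower, a share that was also not tested.

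Of 34 measured markers of other cell types 1 (2.94%) was called, against 181 of all 16910 genes (1.07%), and the difference was not tested. Esam was the only called gene of 9 measured endothelial markers (Fisher's exact test, adjusted p = 0.308, and 2 called over the list alone), while none of 7 fibroblast, 9 haematopoietic and 9 pluripotency or amnion markers passed by either adjustment, and 0 had an unadjusted p below 0.05. Of 43 measured ribosomal protein genes, Rpl30 rose 1.28-fold (FDR = 7.19e-14) and Rpl34 fell 1.13-fold (FDR = 0.0245) in the authors' deposited table (Fisher's exact test, adjusted p = 0.29, and 3 called over the list alone), and 15 of the 43 had an unadjusted p below 0.05. None of 12 measured mitochondrially encoded transcripts passed, although 5 had an unadjusted p below 0.05 and 4 passed when adjusted over the list alone. Among them was Mt-nd5, 1.33-fold lower (FDR = 0.103 over all transcripts) in the authors' deposited table. Over all 33654 transcripts, 661 had an unadjusted p below 0.05 in the authors' EDGE test. That is a smaller share than among the ribosomal or the mitochondrial genes, and whether abundance underlies this was not tested. None of 8 measured replication-dependent histones passed by either adjustment, and 0 had an unadjusted p below 0.05. Only 9 of the 29 histone symbols occurred in the table.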

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

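The fold minimum was planned for the calls over all transcripts, and its use on the gene lists, like the other alternatives, was chosen after seeing the data. Of the 193 called transcripts, 64 remained with a fold of at least 2 and 103 under Bonferroni correction, because both call fewer by construction. Adjusting over rows with a fold other than 1 gave 213, and counting symbols gave 182. The share of calls that were lower was 71.0%, against 81.2% at a fold of at least 2 and 69.9% under Bonferroni correction. The 1 called extravillous trophoblast marker became 0 at a fold of at least 2. The number of gene lists past an adjusted Fisher p of 0.05 was 4, against 0 at a fold of at least 2, 2 under Bonferroni correction, 2 with a background of genes with a p-value below 1, and 6 when adjusted over rows with a fold other than 1. The log2 fold of Tfpi was -5.24 for Tfpi_1 and -3.24 for Tfpi_2. Other scalings, filters, pseudocounts, tools, set tests with a preset or estimated correlation and leaving out each library were not run, because the library columns matched no labelled library. No paired analysis was possible because the labels share no replicate numbers between groups and no library values were used. The depth behind each fold is unknown here, so a transcript that missed the threshold is not shown to be stable.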

Other observations

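Both tests in this part were chosen after the results were seen. Several called genes outside the fixed lists were picked after their values were seen, and no group was tested. In the authors' deposited table, Hsp90ab1, a cytosolic chaperone, was 1.37-fold higher as Hsp90ab1_1 (FDR = 4.72e-26) and Hsp90aa1 1.13-fold higher (FDR = 0.029), while the small heat shock gene Hspb1 was lower. The nucleolar protein gene Ncl was 1.44-fold higher (FDR = 3.51e-19) and Hmox1, the haem-degrading enzyme, 1.22-fold higher (FDR = 7.2e-06) in the authors' deposited table. Jdp2, which encodes a partner of AP-1 subunits and lies outside the fixed lists, was 1.36-fold lower in the authors' deposited table (FDR = 0.0185).

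The table has rat-type identifiers, while the labels describe human cells and their protocols name a rat reference. Whether the identifiers come from the build named there was not settled, since most of them, 4627 rows, are AABR07 names, which may belong to a later rat assembly. A table of human transcripts on a human reference would hold no rat-type identifier, and 5458 rows carried one (AABR07, RGD, RT1 or rat Ensembl names). Identifiers show the reference and not the source of the RNA, so human RNA aligned to a rat reference was considered next. For this, 4 transcripts of the rodent prolactin family passed the authors' FDR, and these genes have no human counterpart of the same name. Reads align by sequence and not by gene name, so this count cannot decide whether the RNA was human. Another candidate explanation, as a hypothesis, is that the table holds libraries other than the 8 human ones. What the 6 libraries were, beyond their column names, stays open.

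More called transcripts were lower (137) than higher (56), and the median log2 fold over transcripts with a fold other than 1 was 0.0072.

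The immediate early and heat shock list held 5 called genes of 23. Its adjusted Fisher p was 0.00122 against the background of genes with a p-value below 1, but 0.516 under Bonferroni correction, with 1 called gene, and 0.0782 at a fold of at least 2. Neither the abundance of these transcripts nor their quick response to handling was tested.

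Of the 9 genes with more than 1 called transcript, Rtn4 was the only one called in both directions: in the authors' deposited table Rtn4_2 was 1.71-fold higher (FDR = 1.55e-08), Rtn4_4 1.35-fold higher (FDR = 0.0334) and Rtn4_3 1.70-fold lower (FDR = 0.00343). Among the calls, 22 lacked a gene name, of which 20 were lower, and 4 with clone names beginning AABR070150 had sizes between 2.68-fold and 2.94-fold. Of the 21780 transcripts with a fold other than 1, 55.5% had a p-value of exactly 1. The 9 transcripts with a p-value listed as 0 had sizes between 1.24-fold and 37.9-fold. Since the spread between libraries was not examined, such a p-value does not show that a small fold would repeat.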
